A study of Rattus norvegicus with 192 samples.

How the data were processed

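The series measured RNA in hypothalamus, pituitary, thyroid and liver of male rats by 3' bulk RNA barcoding, with 192 libraries in 2 plates of 96 wells. Per the labels' protocols, polyadenylated RNA was barcoded during reverse transcription, pooled, tagmented and sequenced on a NovaSeq instrument. The deposited values were counts per gene and library, given as whole numbers with totals that differed between libraries. BWA 0.7.4.4 and the genome build rn6 were listed, per the submitters' processing notes, without a stated role. The names of the deposited files carry abbreviations that read as unique mapping, RefSeq genes and unique molecular identifiers, which the labels do not explain. The steps between reads and counts were otherwise not given in the sources used here, and no normalization of the deposited counts was apparent. Of 17483 gene names, 15578 matched a RefSeq name table of the assembly GRCr8 directly, 1556 matched through a synonym and 349 did not match. That table was used for names only, and 1323 genes had no count in any library.

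Libraries were grouped by the tissue and treatment in the labels, and every library column was used. Libraries with fewer than 100000 counts were left out, 14 in total, of which 11 were liver, 2 thyroid and 1 hypothalamus. No further library was left out for a profile closer to another tissue. Among those left out, totals ran from 1466 to 28558 in liver and from 4473 to 43573 in thyroid, and the hypothalamus library held 1280 counts. In simulated data for PFOS against vehicle, recovery of 1.5-fold and 2-fold changes was lowest in liver. There, 31.8% of genes changed 1.5-fold, 80.0% of those changed 2-fold and 100% of those changed 4-fold were called among 3154 genes tested.

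Each tissue was fitted on its own with the 4 treatment groups in 1 model, in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr at a minimum count of 10, library sizes were scaled with trimmed mean of M values (TMM) factors, and the quasi-likelihood F test with robust dispersion was applied. The 6 contrasts per tissue were PFOS against vehicle, vancomycin against vehicle, the combination against vehicle, PFOS in vancomycin-treated rats (the combination against vancomycin), vancomycin in PFOS-treated rats (the combination against PFOS) and the interaction. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a contrast, with a threshold of 0.05, and "rose", "fell" and "called" refer to it. The standard error of a log2 fold change was its size divided by the square root of F. Levels in CPM, the counts of a gene scaled to a common library total, are given as group means with the standard deviation (SD). The difference of the PFOS effect between liver and each other tissue was tested as an interaction in 1 edgeR model of both tissues.

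A total of 40 gene lists were fixed, and a list was tested where at least 5 members were measured. The test was camera of limma 3.58.1 with a preset correlation of 0.01, and with a correlation estimated for each list as the alternative. The named genes were chosen by rule. The rule took the 6 largest rises and the 6 largest falls per contrast (10 and 10 for liver under PFOS) among called genes with a mean count of at least 5 in the higher group, set genes of the thyroid axis in each tissue, up to 4 members of each other list by p-value, and up to 5 genes called in several tissues. Genes named outside the rule, such as those left under an alternative, were chosen after their values were seen.

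The tests, the gene lists, the rule for named genes and 8 alternatives per contrast were fixed before the data were examined. These alternatives were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, limma voom with sample quality weights, a fit of only the 2 groups compared, a minimum depth of 500000 counts, all libraries kept, and the well column as a factor. For differences between tissues, the animal number as a replicate block was planned as well. Added after the data were seen were log2 depth as a covariate, the number of G and C bases of the 6-base well barcode as a covariate, a fit without libraries of unusual barcode GC content, and thinning of every library to a common depth. Usual GC content was 1 base in hypothalamus and thyroid and 5 bases in pituitary and liver. The main fit, the gene list test at the preset correlation and the test between tissues were tried on simulated data. In these data 200 genes were changed by known folds, and each gene was drawn independently of the others. The barcode settings, the minimum depth of 500000 counts, all libraries kept and the estimated correlation were not simulated. Up to 100 other splits of the same libraries were refitted for every contrast. Comparisons of single values used two-sided exact permutation tests, and correlations across libraries used permutation tests.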

Results

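Gene expression was profiled in hypothalamus, pituitary, thyroid and liver of adult male rats of the Crl:CD(SD) stock. The animals received corn oil as vehicle, the glycopeptide antibiotic vancomycin, the perfluorinated surfactant PFOS (perfluorooctane sulfonate), or both compounds together. Gavage was given daily for 7 days, from postnatal day 56 to 62, at 3 mg PFOS and 8 mg vancomycin per kg body weight. The assay was 3' bulk RNA barcoding sequencing (BRB-seq), in which the RNA of each sample carries its own barcode before the samples are pooled. The table held counts for 17483 genes in 192 libraries, with 12 libraries for each of the 4 treatments in each of the 4 tissues. Each treatment filled its own plate row within a tissue, so treatment and plate row cannot be told apart.

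After removal of 14 libraries with fewer than 100000 counts, 178 remained. The numbers kept for vehicle, vancomycin, PFOS and the combination were 12, 12, 12 and 11 in hypothalamus, 12 in each group in pituitary, 12, 12, 10 and 12 in thyroid, and 9, 10, 8 and 10 in liver. Total counts of the kept libraries ranged from 172700 to 1240091 in hypothalamus (median 726925), from 231929 to 2804779 in pituitary (median 517282), from 208981 to 1136183 in thyroid (median 501447) and from 106742 to 3387946 in liver (median 481289). Depth differed between treatment groups. In hypothalamus the mean total was 905430 ± 245250 (SD, n = 12) for vehicle, 700530 ± 221230 (n = 12) for PFOS and 532570 ± 176850 (n = 11) for the combination, and in thyroid the corresponding means were 797240 ± 294170 (n = 12), 506270 ± 112230 (n = 10) and 378580 ± 111730 (n = 12).

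Pituitary, thyroid and liver each carried abundant transcripts of their own. Growth hormone (Gh1) made up 29.1 ± 5.28% of the counts in pituitary (mean ± SD, n = 48), thyroglobulin (Tg), the protein scaffold of thyroid hormone, 5.33 ± 1.25% in thyroid (n = 46), and albumin (Alb) 6.40 ± 1.17% in liver (n = 37). The thyroid libraries also held parathyroid hormone (Pth, 4.20 ± 1.40%) and calcitonin (Calca, 0.807 ± 0.213%) transcripts, so parathyroid tissue and C cells were part of these samples.

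The series title concerns disruption of the thyroid hormone system by PFOS and its specificity to organs. The first question was therefore which genes PFOS altered in liver, where drug-metabolising enzymes clear thyroid hormone. PFOS raised transcripts of xenobiotic metabolism and of fatty acid oxidation in liver (n = 8 against n = 9 vehicle). Cyp2b1 and Cyp2b2, cytochromes P450 inducible by phenobarbital through the nuclear receptor CAR, rose by 3.87 ± 0.44 (log2 fold change ± SE, edgeR adjusted p = 3.82e-07) and 2.27 ± 0.23 (adjusted p = 4.02e-09). The Cyp2b1 level was 22.1 ± 17.4 CPM (mean ± SD) under vehicle and 346 ± 257 CPM under PFOS, and that of Cyp2b2 was 110 ± 44.9 and 528 ± 207 CPM. All 8 PFOS libraries lay above the vehicle mean for both genes. The sequences of these paralogs are nearly identical, so how their reads were divided is uncertain.

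Of the 21 measured members of the list of drug metabolism under CAR and PXR, 6 rose and 0 fell, or 11 and 0 when adjusted over the list alone. The list rose as a whole with a median log2 fold change of 0.55 (camera adjusted p = 1.35e-11, and adjusted p = 0.00345 with an estimated correlation). Beside the Cyp2b pair, Aldh1a7, an aldehyde dehydrogenase inducible by phenobarbital, rose by 2.04 ± 0.43, Cyp2c6v1 by 1.02 ± 0.16, Cyp3a2 by 0.81 ± 0.18 and the glucuronosyltransferase Ugt2b1 by 0.85 ± 0.17 (edgeR adjusted p = 0.0141, 0.000164, 0.0188 and 0.00433). The level of Cyp2c6v1 was 2077 ± 653 CPM under vehicle and 4220 ± 1170 CPM under PFOS. Outside the list, the carboxylesterase Ces2a rose by 1.01 ± 0.24 and the secreted inhibitor transcript Spink1l by 1.04 ± 0.26, with 7 and 6 of 8 PFOS libraries above the vehicle mean.

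Peroxisomal fatty acid oxidation and omega-hydroxylation, the classical targets of PPARα, also rose. Among 21 measured members, 3 rose and 0 fell (6 and 1 when adjusted over the list alone), with a median of 0.44 (camera adjusted p = 4.66e-07, and adjusted p = 0.0307 with an estimated correlation). The thiolase Acaa1b rose by 2.55 ± 0.44, the fatty acid omega-hydroxylase Cyp4a1 by 1.10 ± 0.21 and the dienoyl-CoA isomerase Ech1 by 0.85 ± 0.20, each above the vehicle mean in 8 of 8 libraries (edgeR adjusted p = 0.000571, 0.00294 and 0.0193). Acaa1b was scarce, at 3.52 ± 3.00 CPM under vehicle and 23.7 ± 11.7 CPM under PFOS. The epoxide hydrolase Ephx2 rose by 1.47 ± 0.37 and the mitochondrial enoyl-CoA isomerase Eci1 by 1.20 ± 0.23. Eci1 was the 1 riser among 19 measured genes of mitochondrial fatty acid oxidation (4 when adjusted over the list alone). That list had a median of 0.22 and passed the test at a preset correlation (camera adjusted p = 0.000728, but adjusted p = 0.165 with an estimated correlation).

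**Figure D1:**
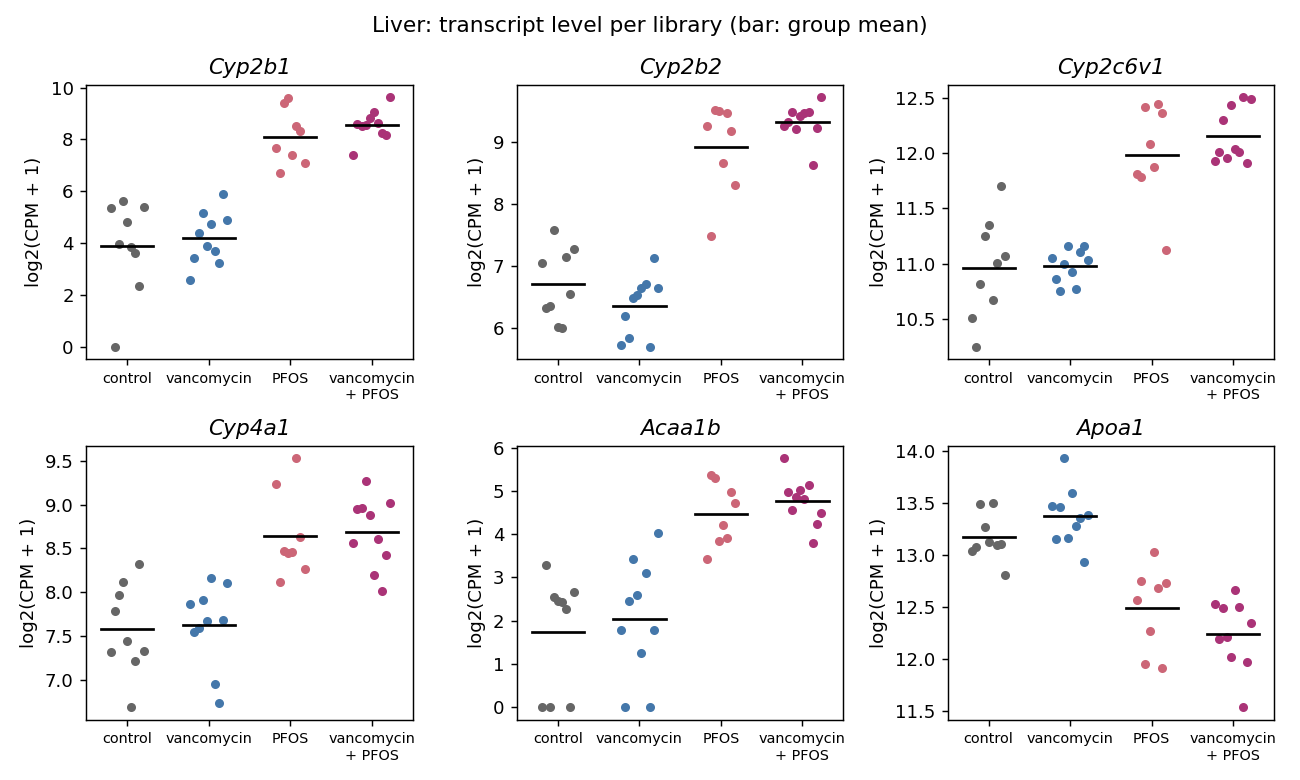
Levels of Cyp2b1, Cyp2b2, Cyp2c6v1, Cyp4a1, Acaa1b and Apoa1 in liver as log2 of CPM plus 1, for control (corn oil vehicle), vancomycin, PFOS and the combination, with 1 point per library and a bar at the mean of each group. The mean levels of Cyp2b2 were 110, 84.9, 528 and 646 CPM in that order.

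Of the genes that fell in liver, Apoa1, the main protein of high-density lipoprotein, was lower by 0.65 ± 0.16 from 9303 ± 1454 to 5934 ± 1573 CPM (edgeR adjusted p = 0.0303), and the glycolytic enzyme Pklr fell by 0.91 ± 0.21 from 313 ± 86.7 to 165 ± 76.2 CPM (adjusted p = 0.0193), each in 8 of 8 libraries. The acetyl-CoA acetyltransferase Acat2 fell by 0.81 ± 0.21 and was the 1 called gene of 20 measured in cholesterol synthesis. That list had a median of -0.34 (camera adjusted p = 7.08e-06, but adjusted p = 0.142 with an estimated correlation). Fatty acid synthesis (8 measured, 0 called, median -0.38) and plasma proteins (25 measured, 1 fell, median -0.19) passed downward at the preset correlation (adjusted p = 0.00237 and 0.00393), with adjusted p = 0.215 and 0.309 with an estimated correlation. Oxidative phosphorylation (25 measured, 0 called, 3 higher when adjusted over the list alone) had a median of 0.24 (adjusted p = 1.31e-05, but adjusted p = 0.197 with an estimated correlation). Other large falls included those of Tmem125 (-1.92 ± 0.50), the adhesion protein vinculin (Vcl, -1.32 ± 0.34), the AP-1 subunit Jund (-1.16 ± 0.29), Coa5 (-0.99 ± 0.22), Tsc22d1 (-0.87 ± 0.23), the acetyltransferase Naa50 (-0.80 ± 0.21) and the matrix protein gene Dpt (-0.71 ± 0.17).

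The hepatic genes of thyroid hormone metabolism showed 1 call. Of 12 measured members of that list, Ugt2b1 rose, and 1 passed when adjusted over the list alone. The deiodinase Dio1 was at 140 ± 22.2 CPM under vehicle and 112 ± 19.5 CPM under PFOS (-0.32 ± 0.14, adjusted p = 0.368), the thyroid hormone-responsive gene Thrsp differed by -0.13 ± 0.33 (adjusted p = 0.962) and the carrier protein gene Ttr by -0.10 ± 0.17 (adjusted p = 0.903). Ugt1a1, with 61 counts over all liver libraries, and Serpina7, with 0, were too scarce to test.

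In all, 27 of 3250 genes passed in liver under PFOS, 14 higher and 13 lower. Of the 9 vehicle livers, 5 carried barcodes whose GC content differed from the usual 5 bases of the liver libraries. Without those 5 libraries 5 genes passed, all higher, namely Cyp2b1, Cyp2b2, Cyp3a2, Cyp4a1 and Acaa1b, and at a minimum depth of 500000 counts 6 passed, all higher, namely Cyp2b1, Cyp2b2, Cyp2c6v1, Cyp4a1, Acaa1b and Ugt2b1.

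The same PFOS dose was tested against an independent set of livers, from rats that also received vancomycin (n = 10 in both groups, no library shared with the comparison above). Cyp2b1 rose by 4.21 ± 0.40, Cyp2b2 by 2.91 ± 0.22, Acaa1b by 2.32 ± 0.35 and Aldh1a7 by 1.96 ± 0.37, each in 10 of 10 libraries (edgeR adjusted p = 3.56e-09, 1.01e-13, 2.15e-05 and 0.00232). Further rises were in Cyp3a9 (1.72 ± 0.37), the pantetheinase Vnn1 (1.18 ± 0.25), Alas1, the first enzyme of haem synthesis (1.03 ± 0.24), and the bile acid racemase Amacr (0.80 ± 0.20). Abi2 had a fold change of 3.08 ± 0.77 with 7 of 10 libraries above the mean of the vancomycin group and a level of 170 ± 307 CPM. Apoa1 fell by 1.12 ± 0.15, Pklr by 0.83 ± 0.19 and the plasma protein fetuin-A (Ahsg) by 0.46 ± 0.11.

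Of the 21 measured drug metabolism genes, 12 rose and 0 fell in that comparison (13 and 1 when adjusted over the list alone), with a median of 0.74 (camera adjusted p = 3.67e-23, and adjusted p = 1.9e-05 with an estimated correlation). The peroxisomal list again had 3 risers (6 when adjusted over the list alone) and a median of 0.38 (adjusted p = 1.67e-09, and adjusted p = 0.00717 with an estimated correlation). The plasma protein list had 1 gene higher, the acute phase protein Orm1 (0.53 ± 0.13), and 2 lower (adjusted p = 2.45e-05, but adjusted p = 0.158 with an estimated correlation). Beside these lists, blood cell markers had 0 called genes of 7 measured and a median of -0.31 (adjusted p = 0.000183, but adjusted p = 0.189 with an estimated correlation). In total 30 genes passed, 27 higher and 3 lower. The comparison shared 13 calls with that of PFOS against vehicle, 11 higher and 2 lower, where independent lists of those sizes would share 0.116 and 0.012. All 27 genes called against vehicle had the same sign here. At a minimum depth of 500000 counts 10 genes passed.

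**Figure D2:**
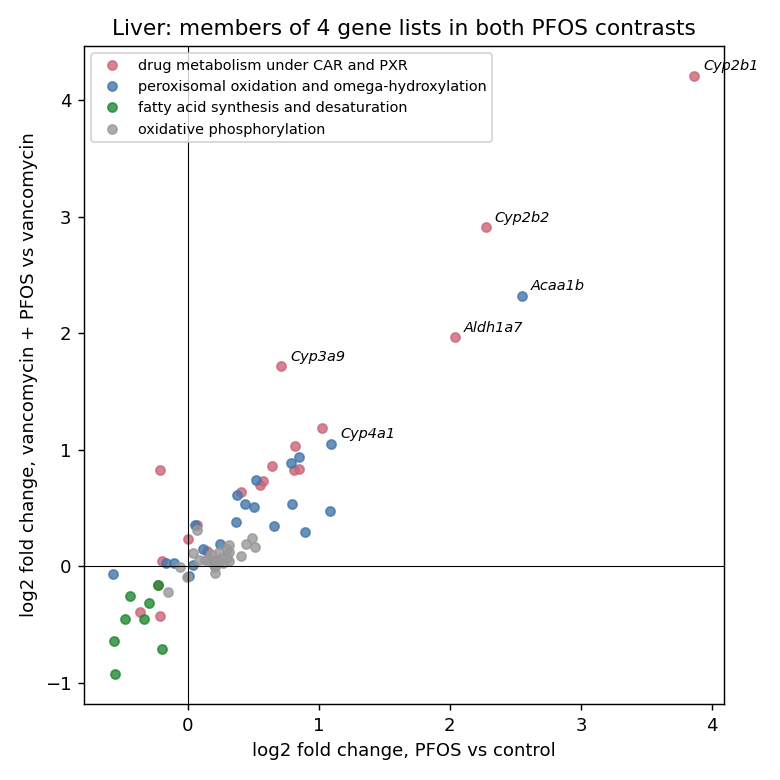
Log2 fold changes in liver of the measured members of 4 gene lists, with PFOS against control (corn oil vehicle) on the x axis, the combination against vancomycin on the y axis and 1 point per gene. Cyp2b1 lay at 3.87 and 4.21 and Cyp2b2 at 2.27 and 2.91.

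The combination against vehicle in liver (n = 10 and 9) gave rises of 4.07 ± 0.43 for Cyp2b1, 2.56 ± 0.23 for Cyp2b2, 2.81 ± 0.41 for Acaa1b, 2.04 ± 0.41 for Aldh1a7, 1.24 ± 0.27 for Vnn1 and 1.16 ± 0.16 for Cyp2c6v1. Large falls included those of the fatty acid-binding protein gene Fabp5 (-1.76 ± 0.41), Otub2 (-1.51 ± 0.39), Poldip3 (-1.25 ± 0.30), Pklr (-1.13 ± 0.20) and Elavl1 (-0.98 ± 0.24). Of the drug metabolism genes 7 rose (12 when adjusted over the list alone; camera adjusted p = 8.99e-18, and adjusted p = 0.000172 with an estimated correlation). Blood cell markers also moved here, with 0 called genes of 7 measured (4 lower when adjusted over the list alone) and a median of -0.70 (adjusted p = 3.39e-06, but adjusted p = 0.136 with an estimated correlation). In total 25 genes passed by edgeR, 14 higher and 11 lower. Without the vehicle livers of unusual barcode GC content 7 passed, 6 higher and 1 lower, and 0 of the 5 falls named here were among them.

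In hypothalamus the comparison of PFOS with vehicle (n = 12 each) asked whether the compound altered the central part of the thyroid axis. Thyrotropin-releasing hormone (Trh) was at 220 ± 38.4 CPM under vehicle and 195 ± 63.8 CPM under PFOS (-0.18 ± 0.16, edgeR adjusted p = 0.549), and the deiodinase Dio2 differed by -0.03 ± 0.18 (adjusted p = 0.96). Dio3, with 9 counts in total, and Crh, with 248, were too scarce to test. Of the 24 measured genes of hypothalamic neuropeptides and thyroid hormone action 0 passed, also when adjusted over the list alone. The list had a median of -0.14 (camera adjusted p = 0.0195, but adjusted p = 0.974 with an estimated correlation).

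Outside that list, 288 of 6596 hypothalamic genes passed, 76 higher and 212 lower. The largest rises were in Qrich1 (0.93 ± 0.24), the ERK phosphatase Dusp6 (0.92 ± 0.23), the KIT ligand gene Kitlg (0.92 ± 0.27), Lrtm2 (0.83 ± 0.24), Elmo1 (0.77 ± 0.21) and the ubiquitin ligase Wwp2 (0.76 ± 0.23). The largest falls were in Pnma8b (-1.72 ± 0.38), the neural transcription factor Pou3f3 (-1.43 ± 0.38), Tmed5 (-1.43 ± 0.42), Zfp474 (-1.29 ± 0.32), Smim17 (-1.24 ± 0.31) and the neuronal adhesion protein Negr1 (-1.23 ± 0.25). Among marker lists, Gad2, an enzyme of GABA synthesis, fell by 1.06 ± 0.32 as the 1 call of 7 measured neuron markers, and the myelin gene Mobp fell by 0.59 ± 0.15 as the 1 call of 8 oligodendrocyte markers (list adjusted p = 0.82 for each). Calreticulin (Calr) fell by 0.22 ± 0.07 and the complex I subunit Ndufc2 by 0.32 ± 0.08. With log2 depth as a covariate 2 genes passed, Rpl7 (-0.33) and Slc38a1 (-1.03), at a minimum depth of 500000 counts 158, and after thinning of every library to a common depth 100.

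PFOS in vancomycin-treated rats (n = 11 and 12) gave 516 calls in hypothalamus, 194 higher and 322 lower. The largest rises were in Rnf121 (0.97 ± 0.24), Mob1a (0.85 ± 0.27), Slc3a1 (0.81 ± 0.18), Cyb561a3 (0.78 ± 0.24), Coa5 (0.75 ± 0.16) and the mitotic kinesin Kif20a (0.74 ± 0.24). The largest falls were in Ybx3 (-1.32 ± 0.29), Ddx3 (-1.17 ± 0.37), the dynamin gene Dnm3 (-1.13 ± 0.29), the early endosome protein Eea1 (-1.13 ± 0.37), Ppp1r35 (-1.12 ± 0.29) and Bai1 (-1.11 ± 0.33). Myelin genes fell: Mobp by 0.84 ± 0.16, Mbp by 0.57 ± 0.14 and Mag by 0.60 ± 0.18, 3 of 8 oligodendrocyte markers (4 when adjusted over the list alone; camera adjusted p = 0.0225, but adjusted p = 0.957 with an estimated correlation). Blood cell markers moved in the same comparison, with 1 of 7 measured lower and a median of -0.32 (adjusted p = 0.0225, but adjusted p = 0.957 with an estimated correlation), at 0.539 ± 0.0769% of the counts under vancomycin and 0.443 ± 0.104% under the combination. The thyroid hormone receptor gene Thra fell by 0.60 ± 0.17 from 78.9 ± 20.6 to 53.6 ± 16.1 CPM (adjusted p = 0.0193), the 1 call among the 24 axis genes. Oxidative phosphorylation had 1 gene higher and 4 lower (median -0.10, adjusted p = 0.0328, but adjusted p = 0.957 with an estimated correlation). Of these calls, 128 were shared with PFOS against vehicle in the same direction, 28 higher and 100 lower, where independent lists would share 2.24 and 10.3. Many of the shared falls were in ribosomal protein genes. Examples named after their values were seen were Rpl7 (-0.37 against vehicle, -0.26 here) and Rps12 (-0.73 and -0.89). The PFOS group had the lower mean total in both comparisons, so the overlap does not separate PFOS from depth. With log2 depth as a covariate 121 genes passed, and 317 without the 5 combination libraries of unusual barcode GC content.

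The combination against vehicle gave 537 calls in hypothalamus, 198 higher and 339 lower. Rpusd2 (1.06 ± 0.30), Igsf3 (0.84 ± 0.25), Agk (0.76 ± 0.19), Tmem215 (0.76 ± 0.21), Slc3a1 (0.75 ± 0.17) and Lrrc61 (0.74 ± 0.17) rose most. Pou3f3 (-1.37 ± 0.41), Dtx3l (-1.32 ± 0.32), the postsynaptic scaffold gene Shank1 (-1.30 ± 0.42), Pdcl (-1.25 ± 0.23), Abcc9 (-1.23 ± 0.40) and Pnma8b (-1.22 ± 0.39) fell most. Pro-opiomelanocortin (Pomc) fell by 0.54 ± 0.16 (adjusted p = 0.0308), again the 1 call among the axis genes. Pomc was also abundant in pituitary, whose libraries lay on the same plate, and hypothalamus held 1.53% of the pituitary share of Gh1. How much of the Pomc count in hypothalamus libraries came from pituitary was not tested, so a change in hypothalamic Pomc is not established. Of 7 measured blood cell markers 4 fell (6 when adjusted over the list alone; camera adjusted p = 0.000179, but adjusted p = 0.592 with an estimated correlation), among them beta-globin (Hbb) by 0.70 ± 0.14. Of 9 measured macrophage markers 2 fell (7 when adjusted over the list alone; median -0.35, camera adjusted p = 0.0401, but adjusted p = 0.592 with an estimated correlation). With log2 depth as a covariate 52 genes passed.

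In pituitary, PFOS left the transcripts of the thyrotropin subunits near their vehicle levels (n = 12 each). Tshb was at 7562 ± 3070 CPM under vehicle and 7349 ± 3095 CPM under PFOS (-0.04 ± 0.22), and Cga differed by -0.14 ± 0.12, the thyrotropin-releasing hormone receptor gene Trhr by -0.28 ± 0.25 and Dio2 by -0.31 ± 0.21 (edgeR adjusted p = 1, 0.98, 0.98 and 0.98). None of the 17 measured axis genes passed, and 0 passed when adjusted over the list alone. Over all 4380 genes 52 passed, 0 higher and 52 lower. The largest falls were in Zfp280b (-1.58 ± 0.32), the heparan sulfate sulfotransferase Hs6st1 (-1.52 ± 0.29), the phosphatase Ptp4a2 (-1.52 ± 0.26), Poldip3 (-1.48 ± 0.28), Fbxo21 (-1.47 ± 0.26) and the stress phosphatase subunit Ppp1r15b (-1.46 ± 0.31). Single members of fixed lists were the peroxisomal transporter Abcd3 (-1.20 ± 0.25), Srebf2, the master regulator of cholesterol synthesis (-0.80 ± 0.18), and the endoplasmic reticulum co-chaperone Dnajb9 (-0.92 ± 0.18), and none of those lists passed as a whole (camera adjusted p = 0.686, 0.304 and 0.686).

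The vehicle group set these pituitary falls apart from the liver rises. Of the 12 vehicle libraries 5 carried barcodes of unusual GC content, and within the vehicle group the called genes averaged 7.13 log2 CPM in those 5 libraries and 5.95 in the other 7. Without the 5 libraries 0 of 4846 genes tested passed, and 0 of 4380 with barcode GC content as a covariate.

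PFOS in vancomycin-treated rats gave 0 calls in pituitary by edgeR (n = 12 each; 295 genes at an unadjusted p under 0.05; DESeq2 and voom also gave 0). In edgeR fits of only the 2 groups 3 genes fell, and 2 fell in each of both barcode settings, Mrpl51 (-0.95) and Elavl1 (-0.72 with barcode GC content as a covariate), which were chosen after their values were seen. Of the 52 genes called against vehicle, 51 had the same sign there. The combination against vehicle gave 60 calls, 1 higher (Ppp1r7, 0.82 ± 0.20) and 59 lower, led by Zfp280b (-1.86 ± 0.32), Mrpl51 (-1.71 ± 0.26), Poldip3 (-1.59 ± 0.28), Tmem265 (-1.54 ± 0.29), Traf3 (-1.47 ± 0.31) and Fbxo21 (-1.46 ± 0.25). None of these calls was left without the 5 vehicle libraries of unusual barcode GC content, where the count was 0.

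**Figure D3:**
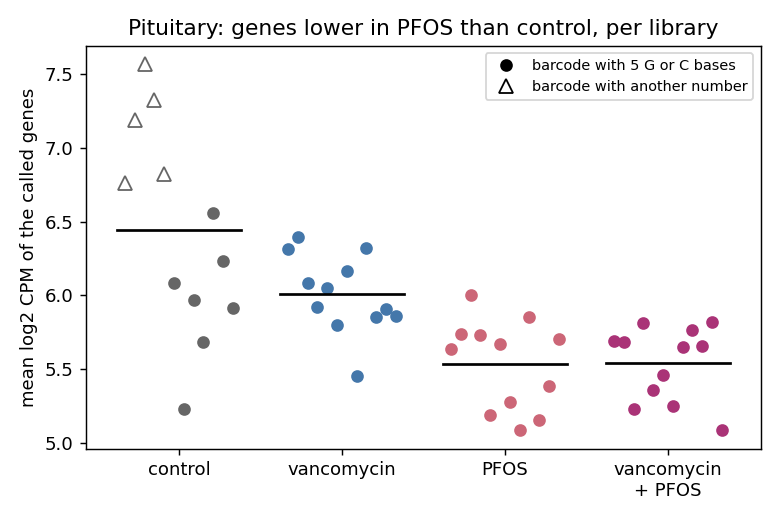
Mean log2 CPM of the 52 genes called in pituitary under PFOS against control (corn oil vehicle), with 1 point per library, a bar at the mean of each treatment group, and triangles for barcodes with a number of G and C bases other than 5. Within the control group the 5 libraries of unusual barcode GC content averaged 7.13 and the other 7 averaged 5.95.

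In thyroid, the genes of hormone synthesis did not pass under PFOS alone (n = 10 against 12). Tg was at 48407 ± 12369 CPM under vehicle and 62342 ± 8769 CPM under PFOS (0.37 ± 0.12, edgeR adjusted p = 0.146). The sodium iodide symporter Slc5a5 differed by 0.10 ± 0.17, the thyrotropin receptor Tshr by 0.08 ± 0.15 and Dio1 by -0.08 ± 0.10. Of the 19 measured genes of hormone synthesis 0 passed, also when adjusted over the list alone (list adjusted p = 0.492). Of 5091 genes 3 passed: Depp1, a gene under FOXO control, rose by 1.04 ± 0.19 (adjusted p = 0.00868, 9 of 10 libraries), and Pa2g4 fell by 1.44 ± 0.29 and Smndc1 by 0.78 ± 0.17, each in 10 of 10 libraries. DESeq2 called 93 genes, and its independent filtering gave these 3 no adjusted p-value. All 3 passed with voom, with no filter, with only the 2 groups, with all libraries kept and in both barcode settings, and 0 of the 3 with log2 depth as a covariate or with the well column as a factor. After thinning only Depp1 was still measured (adjusted p = 0.0595).

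In vancomycin-treated rats the thyrotropin receptor transcript was higher with PFOS, a call that was lost with log2 depth as a covariate. Tshr rose by 0.53 ± 0.15 from 82.8 ± 19.9 to 119 ± 38.1 CPM (n = 12 each, edgeR adjusted p = 0.0391), with 10 of 12 libraries above the vancomycin mean. Adjusted over the list alone, 4 genes of hormone synthesis were higher and 1 lower: Tshr, Duoxa1 (0.41 ± 0.15), which serves hydrogen peroxide supply, the thyroid transcription factors Nkx2-1 (0.44 ± 0.16) and Foxe1 (0.45 ± 0.16), and the protease Ctsl (-0.31 ± 0.10). The list as a whole did not pass (median 0.19, camera adjusted p = 0.115). In total 165 genes passed, 43 higher and 122 lower, and with no filter on low counts 137, 8 higher and 129 lower. Coq8a (0.81 ± 0.23), Glud1 (0.70 ± 0.19), Lrrc41 (0.67 ± 0.18), Gskip (0.65 ± 0.17), Spats2 (0.65 ± 0.20) and Pdrg1 (0.64 ± 0.15) rose most. Ptpre (-1.46 ± 0.31), Pick1 (-1.20 ± 0.30), utrophin (Utrn, -1.17 ± 0.32), the casein kinase subunit Csnk2a1 (-1.10 ± 0.29), dyskerin (Dkc1, -1.06 ± 0.28) and Cnot4 (-1.04 ± 0.30) fell most. With log2 depth as a covariate 0 genes passed, Tshr among those lost, and 84 passed with the well column as a factor.

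The combination against vehicle gave 142 calls in thyroid, 48 higher and 94 lower (n = 12 each), and with no filter on low counts 136, 8 higher and 128 lower. Zc3hc1 (0.88 ± 0.26), Fbxo38 (0.86 ± 0.24), Trmt61a (0.83 ± 0.24), Ppp2r3c (0.73 ± 0.19), Pdrg1 (0.70 ± 0.14) and the mitochondrial ribosomal gene Mrpl1 (0.66 ± 0.14) rose most. Siah1 (-1.30 ± 0.37), Utrn (-1.20 ± 0.31), Ptpre (-1.20 ± 0.31), Styxl1 (-1.09 ± 0.32), Csnk2a1 (-1.05 ± 0.28) and Gtf2f1 (-1.01 ± 0.27) fell most. Of the genes of hormone synthesis 0 passed, while 3 were higher and 2 lower when adjusted over the list alone: Tshr (0.40 ± 0.15), Duoxa1 (0.44 ± 0.14), the proteases Ctsb (0.29 ± 0.10), Ctsk (-0.56 ± 0.19) and Ctsl (-0.30 ± 0.10). Blood cell markers had a median of -0.45 (0 called, camera adjusted p = 0.00087, but adjusted p = 0.585 with an estimated correlation). After adding log2 depth as a covariate 0 genes passed, and 135 of the 142 kept their sign. Of the named genes, Siah1 and Ptpre then took the opposite sign, 0.33 and 0.17.

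Vancomycin alone gave few called genes. Against vehicle it gave 0 calls by edgeR in hypothalamus, thyroid and liver, with 184, 131 and 98 genes at an unadjusted p under 0.05, and DESeq2 and voom also gave 0 in each. Some gene lists passed at the preset correlation, and 0 with an estimated correlation. In hypothalamus these were oxidative phosphorylation and blood cell, macrophage and endothelial markers (camera adjusted p = 0.0117, 0.0153, 0.0431 and 0.0231). In thyroid they were oxidative stress, blood cell and fibroblast markers (adjusted p = 0.0351, 0.022 and 0.0358), and in liver plasma proteins and oxidative phosphorylation (adjusted p = 0.0247 each). In pituitary the actin regulator subunit Arpc4 fell by 0.67 ± 0.13 (adjusted p = 0.0224), and that call was lost without the vehicle libraries of unusual barcode GC content. In PFOS-treated rats vancomycin gave 0 calls by edgeR in any of the 4 tissues, with 490, 122, 318 and 114 genes at an unadjusted p under 0.05 in hypothalamus, pituitary, thyroid and liver. DESeq2 gave 2 calls in thyroid and 0 in the other tissues, and voom gave 0 in all 4. The test of whether the PFOS effect differed with vancomycin gave 0 calls by edgeR, DESeq2 and voom in each of the 4 tissues, with 278, 134, 205 and 58 genes at an unadjusted p under 0.05 in the same order. In simulated data that test recovered 47% of genes changed 2-fold in liver and 69.7% to 77.3% in the other tissues. For 1.5-fold changes it recovered 15.4% in liver, so small differences were not excluded.

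Some gene lists passed the interaction at the preset correlation, each with 0 called genes, and 0 passed with an estimated correlation. In liver these were drug metabolism (median 0.17, camera adjusted p = 0.0201), cholesterol synthesis (0.21, adjusted p = 0.00151), oxidative phosphorylation (-0.19, adjusted p = 0.00105), blood cell markers (-0.55, adjusted p = 4.91e-06) and macrophage markers (-0.21, adjusted p = 0.0168). With an estimated correlation the adjusted p was 0.251 for blood cell markers and 0.448 for the other 4. In hypothalamus they were the axis list (0.07, adjusted p = 0.0146), oligodendrocyte markers (-0.25, adjusted p = 0.0146) and blood cell markers (-0.23, adjusted p = 0.0224), with adjusted p = 0.895, 0.697 and 0.895 with an estimated correlation.

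Groups of genes nonetheless differed between the combination and PFOS alone. Blood cell markers, chiefly globins, were lower in liver (7 measured, 0 called, 5 lower when adjusted over the list alone, median -0.72, camera adjusted p = 6.04e-13, and adjusted p = 0.0253 with an estimated correlation). Their share of all counts was 0.692 ± 0.156% under PFOS (n = 8) and 0.432 ± 0.145% under the combination (n = 10). The same list had medians of -0.45 in hypothalamus and -0.29 in thyroid (adjusted p = 3.44e-07 and 6e-05, but adjusted p = 0.161 and 0.303 with an estimated correlation). In thyroid the C cell and parathyroid markers were higher under the combination (7 measured, median 0.32, adjusted p = 8.78e-05, and adjusted p = 0.0367 with an estimated correlation). Parathyroid tissue and C cells were part of the thyroid samples. A change in these cells and a change in how much of them was sampled cannot be told apart here. Other lists passed in the same contrast at the preset correlation only, each with 0 called genes. In liver these were cholesterol synthesis (median 0.18, adjusted p = 0.000696) and macrophage markers (-0.09, adjusted p = 0.0068), both with adjusted p = 0.485 with an estimated correlation. In hypothalamus they were the axis list (0.07, adjusted p = 0.00281) and macrophage (-0.28, adjusted p = 0.00281), endothelial (-0.35, adjusted p = 0.00436) and oligodendrocyte markers (-0.18, adjusted p = 0.00449), with adjusted p = 0.324, 0.324, 0.13 and 0.294 with an estimated correlation. In thyroid they were the glucocorticoid response (-0.36, adjusted p = 0.0489) and endothelial markers (-0.14, adjusted p = 0.0236), with adjusted p = 0.325 and 0.303 with an estimated correlation.

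Whether the PFOS effect differed between organs was tested directly. The effect in liver differed from that in hypothalamus for 117 of 7193 genes, 83 higher and 34 lower in liver, and from that in thyroid for 49 of 5823 genes, 34 higher and 15 lower. With no filter on low counts the counts were 57 and 11. The planned fit with the sample number as a replicate block also gave far fewer calls, with values in the part on processing. Against hypothalamus, most of those calls were lower in liver. Of the 117 genes, 13 were called in liver and 55 in hypothalamus, and of the 49 genes 11 were called in liver and 0 in thyroid. Between liver and pituitary 0 of 5503 genes passed by edgeR, with 271 at an unadjusted p under 0.05. In simulated data with those libraries the liver and pituitary test recovered 43.9% of the genes changed 2-fold. It could not decide on the liver risers Cyp2b1 and Acaa1b, whose differences of 3.91 and 2.58 had standard errors of 30790 and 7607. The 0 calls therefore do not show that liver and pituitary responded alike. Standard errors were also very large for Acaa1b against thyroid (8545) and Ces2a against hypothalamus (4382).

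Some genes were called in more than 1 tissue under PFOS. Of the 12 such genes, Lpin2, an enzyme of lipid synthesis, rose by 0.61 ± 0.14 in hypothalamus and fell by 1.18 ± 0.25 in pituitary, Zfp644 rose by 0.61 ± 0.14 and fell by 1.44 ± 0.25, and Fam120b rose by 0.58 ± 0.14 and fell by 1.03 ± 0.21. In hypothalamus 0 of these 3 passed with log2 depth as a covariate, and in pituitary 0 genes passed without the vehicle libraries of unusual barcode GC content. Coa5 and Naa50 fell in both pituitary (-1.01 ± 0.24 and -1.03 ± 0.25) and liver. Neither gene passed in either tissue without the vehicle libraries of unusual barcode GC content, which lay in the same well positions on both plates. Across genes, the PFOS fold changes correlated at r = 0.669 between hypothalamus and thyroid and at r = 0.335 between pituitary and liver, and at -0.238 to -0.328 for the other pairs of tissues. Genes are not independent replicates, so no p-value is attached to these values. Hypothalamus and thyroid samples of the same number occupied the same well positions with the same barcodes on the 2 plates, as did pituitary and liver samples.

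**Figure D4:**
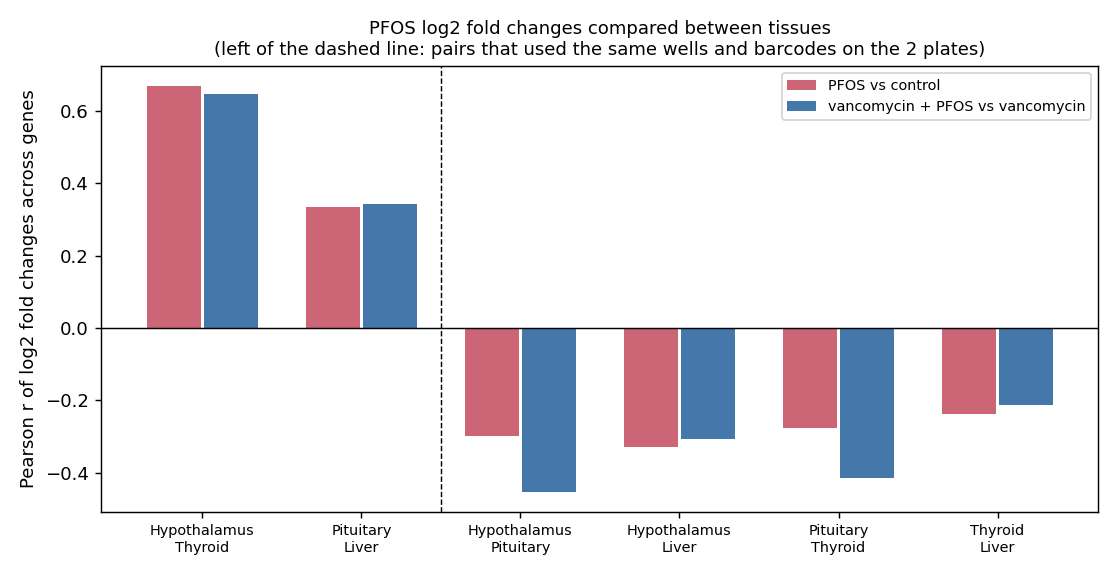
Pearson correlation across genes of the PFOS log2 fold changes between each pair of tissues, for PFOS against control (corn oil vehicle) and for the combination against vancomycin. The pairs left of the dashed line shared well positions and barcodes, and had 0.669 and 0.335 against control and 0.647 and 0.343 in vancomycin-treated rats.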

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

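Of the tests in this part, those of depth and thinning, of barcode GC content as a covariate, of the wells and barcodes in liver, hypothalamus and thyroid, of reads crossing between plates and of the Cyp2b pair were chosen after the result was seen.

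In liver and in the PFOS group of thyroid, 66 groups of values were searched for a single library far from the others. In all, 4 were found where chance gives 3.3, and each was in liver. Acaa1b was at 53.1 CPM in replicate 37 of the combination against 25.2 ± 6.97 CPM (SD, n = 9) in the others, a gap of 0.468 of the group's range. Aldh1a7 was at 88.6 CPM in vehicle replicate 10 against 25.4 ± 11.8 CPM (n = 8), a gap of 0.541. Ttr was at 48923 CPM in vehicle replicate 7 against 27178 ± 2606 CPM (n = 8), a gap of 0.679. Replicate 46 of the combination held 3387946 counts against 562490 ± 338900 (n = 9), a gap of 0.675. A test of the difference of the PFOS effect itself called 117 genes between liver and hypothalamus and 49 between liver and thyroid. The source of the difference from hypothalamus stays open. There, 2 of 288 PFOS calls passed with log2 depth as a covariate, while 76 of the 189 still measured passed after thinning to a common depth. Of the 49 genes, 11 were called in liver and 0 in thyroid, where PFOS against vehicle gave 3 calls. The source of that difference was not tested.

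In liver, 14 genes rose under PFOS, with a median log2 fold change of 1.07. In vancomycin-treated rats, in other libraries, the same genes had a median of 0.96 (0.957), and all 14 had the same sign. For these genes, that argues against the wells of the vehicle group as the cause. Each treatment filled its own plate row, and in both comparisons the PFOS row lay further down the plate. An effect of plate row was therefore not excluded. Against depth, the median was 1.06 with log2 depth as a covariate, and against reads shared within the Cyp2b pair, 10 drug metabolism genes outside that family rose in vancomycin-treated rats. The vehicle livers of unusual barcode GC content differed from the other vehicle livers by -0.10 log2 CPM in these genes (n = 5 and 4, two-sided exact permutation p = 0.627), and with GC content as a covariate the median was 1.10 while its typical standard error grew from 0.23 to 0.30 and 4 of the 14 passed. The genes that fell in liver were not compared in this way. Activation of CAR and PPARα by PFOS may account for the rises and stays a hypothesis, since receptor activation itself was not tested here.

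In pituitary, 52 genes fell under PFOS, with a median of -1.04, and against depth, the median was -0.90 (-0.897) with log2 depth as a covariate and 40 of the 52 passed. The vehicle wells stay open as a candidate explanation, since these genes were 1.18 log2 CPM higher in the 5 vehicle libraries of unusual barcode GC content than in the other 7 (two-sided exact permutation p = 0.00126 over 792 splits). The median under vancomycin against vehicle was -0.60 (-0.595), but the same vehicle libraries served both comparisons, which alone moves it below 0, so it does not decide whether the vehicle group stood apart. With barcode GC content as a covariate the median moved to -0.43, its typical standard error went from 0.24 (0.245) to 0.23, and 0 passed, so the calls ended because the folds shrank. An effect of PFOS of that smaller size was not excluded, since without any vehicle library the genes averaged 6.01 ± 0.268 log2 CPM under vancomycin and 5.54 ± 0.251 under the combination (n = 12 each).

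PFOS calls were most numerous in hypothalamus and, in vancomycin-treated rats, numbered 165 in thyroid. Against reads crossing between plates under the same barcode, thyroglobulin in hypothalamus was at 0.0468% of its share in thyroid. Shared wells and barcodes stay open, since same-numbered hypothalamus and thyroid libraries correlated at a mean of 0.241 within groups, and pituitary and liver libraries at 0.187, while the pairs that shared no well had 0.0334 to 0.0646. The median absolute log2 fold change of the called genes, with log2 depth as a covariate, went from 0.50 (0.497) to 0.39 (0.388) for PFOS against vehicle in hypothalamus, where 2 of 288 passed, from 0.43 to 0.31 for PFOS in vancomycin-treated rats, where 119 of 516 passed, and from 0.47 (0.465) to 0.29 in vancomycin-treated thyroid, where 0 of 165 passed, with typical standard errors of 0.14, 0.11 and 0.12 before and 0.14, 0.10 and 0.11 after. After thinning to a common depth the medians were 0.40 (0.396), 0.38 and 0.45, and 76 of 189, 214 of 416 and 95 of 151 genes still measured passed, so unequal sampling did not account for the calls that passed. What goes with depth cannot be told apart from treatment, as the PFOS groups were shallower in each comparison, and an effect of PFOS stays among the open explanations.

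Other splits of the same libraries, 100 per contrast with the real one included, were refitted to ask how often a random split calls as many genes. The bound was 5 of 100 splits, without adjustment for the number of contrasts. A count under it argues against chance without excluding it. Fewer than 5 splits were as large for PFOS against vehicle in hypothalamus (288 real, 241 the highest other, 1 split as large), in thyroid (3 and 1, 1 split) and in pituitary (52 and 243, 2 splits). The same held for the combination against vehicle in hypothalamus (537 and 487), pituitary (60 and 17), thyroid (142 and 68) and liver (25 and 6), and for PFOS in vancomycin-treated rats in hypothalamus (516 and 163), thyroid (165 and 2) and liver (30 and 1), each with 1 split as large. It also held for the difference of liver from hypothalamus (117 and 169, 2 splits) and from thyroid (49 and 10, 1 split). The bound was reached for PFOS against vehicle in liver alone (27 real, 180 the highest other, 5 splits as large) and for vancomycin against vehicle in pituitary (1 and 1, 6 splits). All 27 of these liver calls had the same sign in vancomycin-treated rats, where 13 of them passed, while 0 of the 3 thyroid calls passed there. For every contrast with 0 calls, all 100 splits were as large, which a real count of 0 fixes in advance. The highest other was 429 for vancomycin against vehicle in hypothalamus, 257 in thyroid and 1 in liver. It was 3, 336, 33 and 40 for vancomycin in PFOS-treated rats in hypothalamus, pituitary, thyroid and liver, 2 for PFOS in vancomycin-treated pituitary, 38, 1, 1 and 1 for the interaction in the same order, and 366 for liver against pituitary. Splits that call several times the real count point to a structure of the libraries, and which structure was not tested.

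Chance cannot be excluded for the numbers of gene lists called, since 5 or more of 100 splits, the real one included, called as many in every contrast with a called list. In hypothalamus 95, 24, 38, 11, 12 and 30 of 100 splits called as many lists as PFOS against vehicle (1 real, 9 the highest other), vancomycin against vehicle (4 and 9), the combination against vehicle (2 and 6), PFOS in vancomycin-treated rats (3 and 7), vancomycin in PFOS-treated rats (5 and 9) and the interaction (3 and 7). In thyroid the numbers were 30 for vancomycin against vehicle (3 and 9), 82 for the combination against vehicle (1 and 8) and 13 for vancomycin in PFOS-treated rats (4 and 6). In liver they were 5 for PFOS against vehicle (7 and 8), 41 for vancomycin against vehicle (2 and 6), 22 for the combination against vehicle (6 and 9), 8 for PFOS in vancomycin-treated rats (7 and 9), 64 for vancomycin in PFOS-treated rats (3 and 10) and 21 for the interaction (5 and 9). Single lists differed in how many of 100 splits, the real one included, had a p-value as small. In liver, for PFOS against vehicle, the combination against vehicle and PFOS in vancomycin-treated rats, these were 1, 1 and 1 for drug metabolism, 3, 1 and 1 for peroxisomal oxidation, 3, 10 and 3 for mitochondrial oxidation and 11, 1 and 2 for fatty acid synthesis. They were 15 and 12 for plasma proteins (PFOS against vehicle and in vancomycin-treated rats), 8 and 21 for oxidative phosphorylation (PFOS and the combination against vehicle), 12 and 14 for blood cell markers (the combination against vehicle and PFOS in vancomycin-treated rats), 4 for cholesterol synthesis (PFOS against vehicle) and 14 for lipid handling (PFOS in vancomycin-treated rats). For vancomycin in PFOS-treated rats, blood cell markers had 1 in liver, 3 in hypothalamus and 8 in thyroid, and C cell and parathyroid markers had 1. In the other contrasts blood cell markers had 9 (interaction) in liver, 14 to 38 in hypothalamus and 17 and 22 in thyroid, and in hypothalamus the axis list had 80 (PFOS against vehicle), 89 (vancomycin in PFOS-treated rats) and 41 (interaction).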

How the results depend on the processing

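The 4 alternatives named in this part as depth covariate, barcode GC covariate, libraries of unusual barcode GC left out and thinning were chosen after seeing the data. Of the named genes' values under the alternatives fixed beforehand, 4934 kept their direction and their side of the threshold, 408 lost the call, 99 gained one and 0 reversed. Of the 30 lost with DESeq2, 29 had no adjusted p-value after its independent filtering, so these were not tested there. Under the added alternatives 2231 kept both, 377 lost the call, 19 gained one and 2 reversed. Of the counts of calls, 154 values fixed beforehand and 57 added values lay within 1.5 times the reported count, and 61 and 39 did not. DESeq2's size factors within edgeR moved no count by that much. Where no cause is named, the cause was not tested.

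With DESeq2, calls numbered 93 for PFOS against vehicle, 309 for the combination against vehicle, 297 for PFOS in vancomycin-treated rats and 2 for vancomycin in PFOS-treated rats in thyroid, and 46 for the combination against vehicle in liver. With voom and quality weights they numbered 776 for PFOS in vancomycin-treated rats in hypothalamus, 408 in thyroid and 58 in liver, and 22 for PFOS against vehicle in thyroid.

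With no filter on low counts, which raises the number of genes tested, hypothalamus gave 165 calls for PFOS against vehicle (31 higher, 134 lower), 356 for the combination against vehicle and 340 for PFOS in vancomycin-treated rats. PFOS against vehicle gave 7 in thyroid and 14 in liver (12 higher, 2 lower), vancomycin against vehicle 0 in pituitary, and the difference of liver from hypothalamus 57 and from thyroid 11.

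At a minimum depth of 500000 counts, hypothalamus gave 158, 259 and 299 calls for PFOS against vehicle, the combination against vehicle and PFOS in vancomycin-treated rats. Pituitary gave 0 for PFOS, vancomycin and the combination against vehicle, with 3 vehicle libraries left. Thyroid gave 37 for PFOS against vehicle and 462 for PFOS in vancomycin-treated rats, with 4 PFOS and 2 combination libraries left. Liver, with 3 vehicle and 3 PFOS libraries left, gave 6 for PFOS against vehicle, 7 for the combination against vehicle and 10 for PFOS in vancomycin-treated rats.

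With all libraries kept, calls numbered 12 for PFOS against vehicle in thyroid, and 14, 14 and 10 in liver for PFOS against vehicle, the combination against vehicle and PFOS in vancomycin-treated rats. No pituitary library had been left out, so this gave no pituitary value. With only the 2 groups compared, pituitary gave 0 for PFOS against vehicle, 0 for vancomycin against vehicle, 30 for the combination against vehicle and 3 for PFOS in vancomycin-treated rats. Thyroid gave 65 and liver 8 (7 higher, 1 lower) for PFOS against vehicle, and liver 15 for the combination against vehicle. That setting has no value for the interaction. With the well column as a factor, PFOS against vehicle gave 169 in hypothalamus and 0 in thyroid, and thyroid gave 65 for the combination against vehicle and 84 for PFOS in vancomycin-treated rats.

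With log2 depth as a covariate, hypothalamus gave 2, 52, 121 and 1 for PFOS against vehicle, the combination against vehicle, PFOS in vancomycin-treated rats and vancomycin in PFOS-treated rats. Pituitary gave 0 for vancomycin and 19 for the combination against vehicle, and thyroid gave 0 for PFOS against vehicle, 0 for the combination against vehicle and 0 for PFOS in vancomycin-treated rats. The combination against vehicle in thyroid then reversed for Siah1 (0.33) and Ptpre (0.17) without passing the threshold. After thinning to a common depth, which lowers the counts of most libraries, hypothalamus gave 100, 264 and 236 for PFOS against vehicle, the combination against vehicle and PFOS in vancomycin-treated rats. Pituitary gave 29 for PFOS and 31 for the combination against vehicle, thyroid 0 for PFOS against vehicle, and liver 12 for PFOS against vehicle (9 higher, 3 lower) and 18 for PFOS in vancomycin-treated rats.

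With barcode GC content as a covariate, hypothalamus gave 299 for the combination against vehicle and 329 for PFOS in vancomycin-treated rats. Pituitary gave 0 for PFOS, 0 for vancomycin and 0 for the combination against vehicle and 2 for PFOS in vancomycin-treated rats, Mrpl51 (-0.95) and Elavl1 (-0.72). Thyroid gave 31, 53 and 80 for PFOS against vehicle, the combination against vehicle and PFOS in vancomycin-treated rats, and liver 4 for PFOS (4 higher) and 7 for the combination against vehicle. Without libraries of unusual barcode GC content, the same comparisons gave 307 and 317 in hypothalamus, 0, 0, 0 and 2 in pituitary, 44, 35 and 85 in thyroid and 5 (5 higher) and 7 in liver.

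The share of rises among the calls moved by more than 10 points in some settings, given here as higher and lower genes. For the combination against vehicle in hypothalamus it was 95 and 261 with no filter and 10 and 42 with log2 depth as a covariate, and for PFOS in vancomycin-treated rats 79 and 261, and 23 and 98. PFOS against vehicle in hypothalamus had 157 and 222 with voom, 157 and 246 with barcode GC content as a covariate, 153 and 220 without unusual barcodes and 0 and 2 with log2 depth. In thyroid it had 13 and 9 with voom, 43 and 22 with only the 2 groups, 23 and 14 at the higher minimum depth, and 22 and 9, and 32 and 12 in the barcode settings. PFOS in vancomycin-treated thyroid had 8 and 129 with no filter, 166 and 242 with voom and 204 and 258 at the higher minimum depth, and the combination against vehicle there 8 and 128 with no filter and 23 and 80 after thinning. In liver, PFOS against vehicle had 6 and 0 at the higher minimum depth, 10 and 4 with all libraries and 13 and 6 with the well column. The combination against vehicle in liver had 18 and 7 with no filter, 12 and 3 with only the 2 groups, 7 and 0 at the higher minimum depth, 14 and 7 with log2 depth and 6 and 1 in each barcode setting. PFOS in vancomycin-treated liver had 40 and 18 with voom, 28 and 8 with only the 2 groups, 17 and 6 with the well column and 14 and 4 after thinning. The difference of liver from thyroid had 23 and 19 with DESeq2's size factors and 9 and 2 with no filter.

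With a correlation estimated for each list, the number of lists called went to 0 in hypothalamus for all 6 contrasts, from 1, 4, 2, 3, 5 and 3. In thyroid it went to 0 for vancomycin and for the combination against vehicle, and to 1 for vancomycin in PFOS-treated rats. In liver it went to 2 for PFOS against vehicle, 2 for the combination against vehicle, 2 for PFOS in vancomycin-treated rats, 1 for vancomycin in PFOS-treated rats, and 0 for vancomycin against vehicle and 0 for the interaction.

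The labels number the samples alike in each tissue but do not state that a number marks an animal. With the number as a replicate block, the difference of liver from hypothalamus gave 29 calls (12 higher, 17 lower), from pituitary 2 and from thyroid 8 (4 higher, 4 lower). Libraries correlated best with their own number in 40 of 45 pairs of hypothalamus and thyroid and in 25 of 37 pairs of pituitary and liver, which share wells. They did so in 10 to 18 pairs for tissues that share none. The lowest correlation of a same-numbered pair with liver was -0.291 with hypothalamus, -0.273 with thyroid and -0.0138 with pituitary, and the reported tests did not pair samples by number. In pairs of tissues that share no well, the mean correlation was 0.0334 to 0.0646 for same numbers and -0.00382 to -0.00701 for others. Pairing by number was therefore not excluded. Same numbers also shared the well column in each tissue, so animal and column cannot be told apart. In simulated data, 2-fold differences of the PFOS effect were recovered for 59.7% of genes against hypothalamus, 43.9% against pituitary and 52.2% against thyroid.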

Other observations

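The tests of reads crossing between libraries were chosen after the result was seen. The test of blood content was chosen before.

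In liver of vancomycin-treated rats, fatty acid synthesis and desaturation under PFOS had 0 called genes among 8 measured (2 fell when adjusted over the list alone) and a median of -0.45 (camera adjusted p = 2.45e-05, but adjusted p = 0.113 with an estimated correlation). Lipid handling under PPAR had 1 riser among 6 measured and a median of 0.41 (adjusted p = 0.0294, but adjusted p = 0.144 with an estimated correlation). Mitochondrial fatty acid oxidation had a median of 0.19 (adjusted p = 5.81e-05, but adjusted p = 0.0992 with an estimated correlation).

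Blood transcripts had negative medians under the combination against PFOS in liver (-0.72), hypothalamus (-0.45) and thyroid (-0.29), while pituitary had -0.07 and held 1.16 ± 0.394% under PFOS and 1.13 ± 0.357% under the combination, and blood left in each animal's tissues is a candidate explanation. If a number marks an animal, which the labels do not state, same-numbered libraries of different tissues should hold correlated shares within groups. Over the 4 pairs of tissues that share no well, the mean correlation was 0.202, between the bound for the explanation and that against it. Hypothalamus and pituitary had r = 0.429 (rho = 0.374, permutation p = 0.00198 and 0.011, adjusted p = 0.00396 over 6 relations, r = 0.274 without the 2 farthest libraries, 47 pairs), and pituitary and thyroid r = 0.462 (rho = 0.338, permutation p = 0.0011 and 0.027, adjusted p = 0.0033, r = 0.524 without the 2 farthest). Liver had r = -0.00982 with hypothalamus (rho = -0.147, permutation p = 0.955 and 0.419) and r = -0.072 with thyroid (rho = -0.127, permutation p = 0.689 and 0.488). Blood left in the animal and a change in the organ cannot be told apart by these values, since liver did not follow the other tissues.

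Transcripts of 1 tissue appeared at low levels in libraries of others. Thyroglobulin was at 0.0468% of its thyroid share in hypothalamus, which used the same barcodes on the other plate, and at 0.000493% in pituitary, a ratio of 94.9. Crossing of reads between plates under the same barcode could give this small share. On the plate they shared, liver held 2.08% of the thyroid share of thyroglobulin, and hypothalamus held 1.53% of the pituitary share of Gh1. The source of these larger shares was not tested, and the counts were not corrected for them.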
